A study of Homo sapiens with 108 samples.

How the data were processed

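Small RNA libraries from colon biopsies stored in RNAlater were analysed from the deposited tables. Per the labels, RNA was extracted with a DirectZOL kit, and libraries were made with a TruSeq small RNA kit (11 libraries) or with NEBNext kits in 2 batches (54 and 43 libraries). STAR, DESeq2 and the genome build hg38 are named in the submitters' processing notes without versions; trimming, filters and the strand setting are not given in the sources used here. The authors deposited 4 tables of normalized read counts, a signal in which each value is the number of reads of a small RNA divided by a size factor of its library. The tables listed 1188 (SSA/P), 1198 (HP), 1219 (AP) and 1241 (control) miRNAs, piRNAs, snoRNAs and other small RNAs, 1093 of them common to all. Size factors were recomputed within each table from median ratios of reads. Log2 ratios of deposited to recomputed factors ran from -0.01 to 0.06 in SSA/P and -0.03 to 0.03 in AP. They ran from -0.11 to 0.01 in HP and -0.07 to 0.19 in control colon, a less close match. Against factors recomputed over the 4 tables, the mean log2 ratio was -0.02 in SSA/P, 0.02 in AP, 0.09 in HP and -0.02 in control colon. The tables were treated as normalized separately, though on average their scales lay close.

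Every value of a library was a whole multiple of the same step in 106 of 108 libraries, where 100% of the values came out whole at a tolerance of 0.01 reads. The reads so recovered gave the depth of each library. In the 2 libraries left, 1 of SSA/P and 1 of HP, the size factor was too close to 1 for that step to be told from rounding, and they were left out of the count models. No pair of libraries of a group agreed within sampling noise (lowest chi-square per degree of freedom 42.6). PCR reads without molecular identifiers are not independent molecules, so read depth bounds counting error only.

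Groups came from the labels. Biopsies that shared the leading code of their description were taken as the same subject and averaged on the log scale within a group. The labels do not say outright that this code is a person, so p-values measure the spread between subject codes. For each comparison within a table, log2(value + 1) was fitted with limma-trend (limma 3.58.1, R 4.3.3), with library batch as a covariate, for features with a mean value of at least 5. P-values are two-sided and adjusted by Benjamini-Hochberg over all features, and miRNAs with an adjusted p under 0.05 were called. Fold changes are on the log2(value + 1) scale, which understates those of low miRNAs. Differences of lesion effects between tables used a lesion by table term with a batch effect for each table. Of the 48 subject codes, 2 had libraries in both the SSA/P and the HP table, and 2 codes of the SSA/P table had libraries in both TruSeq and NEBNext A. Right and left uninvolved colon were pooled. The uninvolved colon of SSA/P was right colon for 11 of 12 subject codes, and that of HP was left colon for 7 of 10. Because the tables were normalized separately, no direct test of a lesion or of uninvolved colon against control colon was made.

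A total of 18 lists of miRNAs (cell types, genomic clusters, families and lists from the literature) were fixed before the data were examined and tested with camera, with a preset correlation of 0.01 and with an estimated one. The named miRNAs follow a rule fixed at the same time: the 10 highest and 10 lowest called miRNAs by fold change with a mean value of at least 20 in the higher group, up to 4 most abundant members of each list, and 12 miRNAs named in advance. The prefix hsa is left out of miRNA names. miR-9-5p, miR-486-5p, let-7 members and other miRNAs with near-identical copies cannot be assigned to a locus. Positions are those of the authors' tables, and host genes come from GENCODE release 29.

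Alternatives fixed in advance were the pseudocount (0.5 or 10), the filter (none, or a mean of 50), TMM or equal-sum scaling, no batch or flow cell as the covariate, each biopsy as a replicate, subject code as a fixed or random block, robust empirical Bayes, NEBNext libraries alone and, for SSA/P, right uninvolved colon alone. Chosen after seeing the data were edgeR's quasi-likelihood test (edgeR 4.0.16) and DESeq2 (1.42.0) on the recovered reads, with each biopsy as a replicate or with reads summed per subject code, the removal of libraries under 2000000 reads, left uninvolved colon alone for HP, right uninvolved colon alone for AP, lists between the cohorts without the batch covariate, and the overlap and lesion difference of SSA/P and HP without the subject codes of both tables. Adjusted p-values that DESeq2 left undefined were kept so (322 features in the comparison of cohorts, and 729 with reads summed per subject code). In control colon the subject codes paired the biopsies: with batch removed, deviations from the group means correlated above 0.1 in 15 of 15 codes (lowest 0.127, median 0.367), and the right biopsy correlated best with the left biopsy of its own code in 12 of 15.

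The fits were tested on simulated reads with 200 changed features per comparison, drawn as if biopsies of a subject code were independent. The spread of each feature was estimated without a batch term, and no batch effect was simulated. Batch differences thus entered as random spread that the batch covariate cannot remove, and the shares called can differ from those of the real fits. limma called 85.9% of 4-fold and 27% of 2-fold changes for SSA/P, 80.6% and 16.2% for HP, 84% and 24.2% for AP, and 85% and 39.4% for control colon. In the same order the false calls were 3, 4, 6 and 6 for limma, 2, 2, 5 and 5 for edgeR and 9, 9, 12 and 12 for DESeq2. For control colon, camera with both correlations called a simulated list of changed features and 0 of 20 unchanged lists. The simulated features were drawn independently of each other, while the estimated correlation of the real 14q32 list was 0.347 there. The simulation therefore cannot tell how often the preset correlation gives false calls for members that vary together. P-values of single list means are from permutation tests, exact for fewer than 15 subject codes and with 100000 draws otherwise.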

Results

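Small RNA was sequenced in 108 colon biopsies that carried 48 subject codes. The biopsies came from 16 sessile serrated adenomas/polyps (SSA/P), 14 hyperplastic polyps (HP), 14 adenomatous polyps (AP), 23 pieces of uninvolved right colon, 11 pieces of uninvolved left colon, and 15 right and 15 left pieces of control colon. SSA/P and HP are serrated polyps of the large bowel, and AP is the conventional adenoma. Of the SSA/P libraries, 10 were of the serrated polyposis cohort and 6 sporadic. The counts were 2 and 12 for HP, and 0 and 14 for AP. Biopsies of a group with the same subject code were averaged for limma, so n counts subject codes, while edgeR and DESeq2 took each biopsy as a replicate (15 of SSA/P for 12 codes, 13 of HP for 12 and 14 of AP for 10, without 2 libraries whose reads were not recovered) except where reads are said to be summed per subject code. The values were normalized read counts in 4 tables, 3 of which held a polyp type with its own uninvolved colon, and the fourth held control colon. The tables had been normalized separately, and tests were run within a table only. Reads per library ranged from 1185788 to 12218297, with a median of 5907325. The range was 1353772 to 8723245 in SSA/P, 1185788 to 7744483 in HP, 1612217 to 7897543 in AP, 1927160 to 12218297 in uninvolved right colon, 1700296 to 8467330 in uninvolved left colon, 1567846 to 8281724 in control right colon and 2154303 to 9853700 in control left colon. miRNAs took a median of 81.8% of the reads in the 11 TruSeq libraries, 87.8% in the 54 libraries of the first NEBNext batch (A) and 97.9% in the 43 of the second (B). Between the groups compared, 24 differences in RNA class shares, in the share of the 5 most abundant features and in reads were tested, and the lowest adjusted p was 0.930 (permutation test, Benjamini-Hochberg). The permutations ignored batch and the pairing by subject code, so they do not show equal composition. The lowest unadjusted p was 0.139 (permutation test), for the 5 most abundant features in AP, at 51.3% against 46.8% in its uninvolved colon.

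The comparison of SSA/P with uninvolved colon asked which miRNAs mark the sessile serrated lesion. Of the 650 miRNAs tested, the highest fitted fold changes were those of both arms of miR-31 and miR-135b, which are described as raised in colorectal tumours. The mean normalized count of miR-31-5p was 853 ± 1041 in SSA/P and 79.5 ± 77.2 in uninvolved colon (SD, n = 12 and 12), a fitted 5.58-fold difference (95% confidence interval 2.04 to 15.2), with the higher value in SSA/P in 9 of 12 subject codes. miR-135b-5p stood at 379 ± 442 against 76.1 ± 106 (SD, n = 12 and 12), a 4.11-fold difference (2.19 to 7.70) seen in 10 of 12 subject codes. The minor arms were far less abundant, at 14.1 ± 23.1 against 1.01 ± 2.04 for miR-31-3p and 14.2 ± 11.1 against 2.76 ± 3.72 for miR-135b-3p (SD). By limma, 0 of 650 miRNAs passed an adjusted p of 0.05 in SSA/P, and 38 had an unadjusted p under 0.05. With subject code as a fixed or a random block, limma called 1 and 13 miRNAs. Without a block, the limma adjusted p was 0.0505 for miR-135b-5p and for miR-135b-3p, and 0.465 for miR-31-5p and for miR-31-3p. Reads recovered from the values gave 4 miRNAs in edgeR's quasi-likelihood test (61 unadjusted), all higher in SSA/P: miR-31-5p (12.6-fold, adjusted p = 0.00284), miR-31-3p, miR-135b-5p (5.06-fold, adjusted p = 0.00317) and miR-135b-3p. DESeq2 on the same reads gave 13 miRNAs (60 unadjusted), 12 of them higher, and among those added were miR-21-3p, miR-486-5p, miR-584-5p, miR-3614-5p, miR-4488 and miR-549a on the higher side and miR-151a-5p on the lower. On reads summed per subject code edgeR and DESeq2 each gave 4 miRNAs, the arms of miR-31 and miR-135b (miR-31-5p adjusted p = 0.0175 and 0.000254), and the other DESeq2 calls ended. The names outside the fixed rule (miR-135b-3p, miR-151a-5p, miR-107, miR-584-5p, miR-3614-5p, miR-4488 and miR-549a) were chosen after their values were seen.

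**Figure D1:**
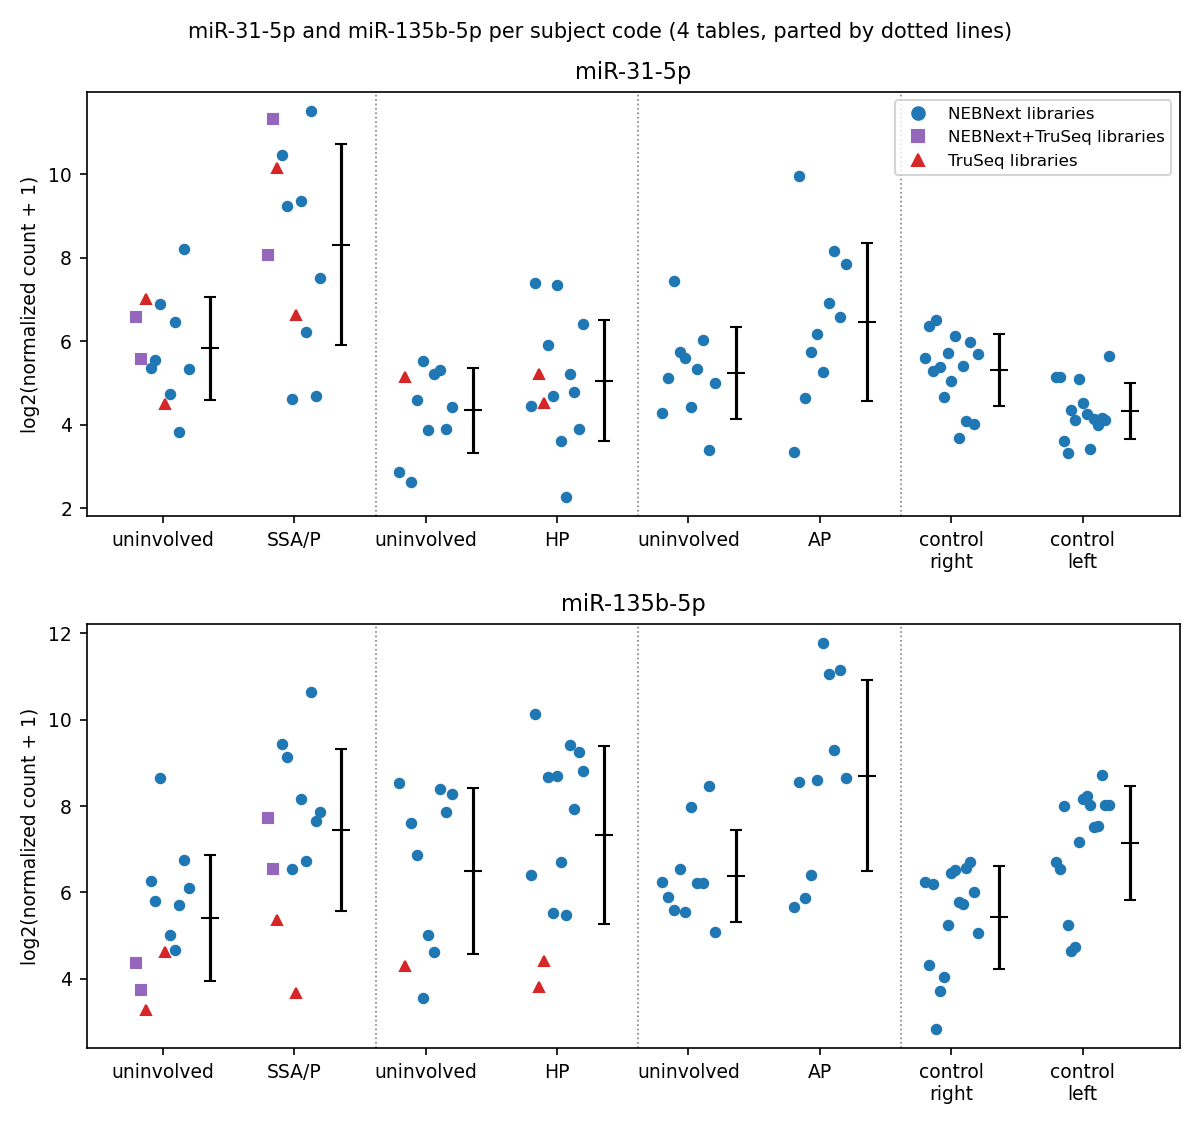
Each point is the mean log2(normalized count + 1) of a subject code, for miR-31-5p (upper panel) and miR-135b-5p (lower panel), with marker shapes for the library kit, the mean and SD of each group as bars and dotted lines between the 4 separately normalized tables. SSA/P averaged 8.31 ± 2.41 for miR-31-5p against 5.83 ± 1.23 in the uninvolved colon of the same table, and the SSA/P points spread from 4.63 to 11.50.

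Within library batches, the log2 fold change of miR-31-5p in SSA/P was 2.65 ± 0.84 (SE) in NEBNext A (n = 7 and 7), 2.12 ± 1.58 in NEBNext B (n = 3 and 3) and 3.02 ± 0.81 in TruSeq (n = 4 and 4). That of miR-135b-5p was 2.34 ± 0.60, 2.53 ± 0.72 and 1.66 ± 0.60 in the same order. Of the 12 subject codes, 2 had libraries in both TruSeq and NEBNext A and count in each. miR-31-5p lies at chromosome 9, 21512158 to 21512178 (hg38), in an intron of MIR31HG, and miR-135b-5p at chromosome 1, 205448361 to 205448383, in an intron of LEMD1. Both are on the minus strand. Among other abundant miRNAs of colon, miR-21-5p had a log2 fold change of -0.05 ± 0.21 (SE), the smooth muscle miRNA miR-143-3p 0.08 ± 0.18, the intestinal miR-192-5p -0.15 ± 0.19 and the enteroendocrine miR-375 0.12 ± 0.20. The sign for miR-21-5p turned in NEBNext libraries alone (0.0244), in edgeR (0.0592) and in DESeq2 (0.0676), and on reads summed per subject code (0.142 and 0.121). Below 0 stood miR-151a-5p (-0.91), miR-107 (-0.67), miR-378a-3p (-0.65) and miR-196b-5p (-0.55), with limma adjusted p-values from 0.785 to 0.922. In NEBNext A, NEBNext B and TruSeq, miR-151a-5p had -1.89 ± 0.52, 0.04 ± 0.27 and -0.38 ± 0.28 (SE), while the values of miR-107 (-0.68, -0.17 and -1.26), miR-378a-3p (-0.72, -0.35 and -0.91) and miR-196b-5p (-0.66, -0.36 and -0.68) were negative in each.

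Of 18 fixed lists, camera called 2 high in SSA/P. In that of miRNAs raised in colorectal tumours in the literature, 14 of 20 members had positive log2 fold changes with a median of 0.24, 6 rose when adjusted over the list alone (limma), and camera gave an adjusted p of 4.73e-05. With an estimated correlation the adjusted p was 0.325. All 4 red blood cell miRNAs had positive values with a median of 0.92, among them miR-451a (16441 ± 11848 against 8579 ± 7241, SD, n = 12 and 12) and miR-486-5p (log2 fold change 0.76 ± 0.27). This list had a camera adjusted p of 0.000250 and 1 member past the threshold adjusted over the list alone. The camera adjusted p of the red blood cell list was 0.325 with an estimated correlation. The miRNAs of the imprinted 14q32 cluster stood low together, with 48 of 53 negative and a median of -0.18 beside -0.07 for all miRNAs (camera adjusted p = 1.58e-07; adjusted p = 0.596 with an estimated correlation). The HOX cluster list (camera adjusted p = 0.00409), the epithelial 200 family (0.00662) and the list lowered in colorectal tumours (0.0477) were also called low with the preset correlation. With an estimated correlation their adjusted p-values were 0.596, 0.596 and 0.598. The intestinal epithelium list had 2 members that rose when adjusted over the list alone, miR-31-5p and miR-31-3p, and a camera adjusted p of 0.623. Camera did not call the remaining lists, with adjusted p-values of 0.0901 for the cluster of miR-183, miR-96 and miR-182, 0.105 for the 29 and 30 families, 0.136 for the 17-92 and paralogue clusters, 0.164 for leukocytes, 0.220 for enteroendocrine and neural miRNAs, 0.596 for let-7, 0.623 for smooth muscle, 0.735 for p53 and methylation-silenced miRNAs and 0.895 for fibroblast and stromal miRNAs. For smooth muscle and for the p53 list the median was above 0 (0.02 and 0.04) while camera pointed down, and with TMM scaling the smooth muscle, stromal and intestinal epithelium medians lay at -0.02, -0.02 and -0.01. The 2 endothelial miRNAs, both arms of miR-126, had a median of -0.28 and the 2 arms of the hypoxia miRNA miR-210 a median of -0.13, too few for camera.

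HP, the common serrated polyp, was compared with the uninvolved colon of its own table (n = 13 and 10). miR-4488 had a log2 fold change of 1.21 ± 0.36 (SE; 2.31-fold, 95% confidence interval 1.39 to 3.83). The value of miR-135b-5p was 0.98 ± 0.44, and 0.29 ± 0.40 against left uninvolved colon alone (n = 13 and 7). Its mean log2 level was 7.33 in HP, 7.41 in left uninvolved colon (n = 7) and 4.40 in right uninvolved colon (n = 3). miR-182-5p of the miR-183 cluster averaged 6515 ± 3815 in HP and 3939 ± 2461 in uninvolved colon (SD), and miR-31-5p averaged 51.5 ± 54.4 against 23.8 ± 14.2. On the low side stood miR-10b-5p at -0.69 ± 0.25, miR-196b-5p at -0.63 ± 0.23, miR-9-5p at -0.50 ± 0.23 and miR-378a-3p at -0.48 ± 0.19. By limma, 0 of 627 miRNAs passed in HP, with 30 at an unadjusted p under 0.05, and each miRNA named for HP so far had an adjusted p of 0.841. edgeR gave 0 miRNAs (44 unadjusted) and DESeq2 gave 0 (56 unadjusted), and both gave 0 on reads summed per subject code. Within NEBNext A (n = 6 and 5) and NEBNext B (n = 5 and 4) the log2 fold change of miR-135b-5p was 1.38 ± 0.77 and 0.84 ± 0.37, that of miR-31-5p 0.35 ± 0.76 and 1.41 ± 0.66, that of miR-4488 0.69 ± 0.51 and 1.37 ± 0.49, that of miR-10b-5p -0.23 ± 0.36 and -1.02 ± 0.35 and that of miR-9-5p -0.08 ± 0.34 and -0.78 ± 0.32. The uninvolved colon of NEBNext B was left colon alone. Against left uninvolved colon alone limma gave 0 miRNAs in HP (79 unadjusted), miR-31-5p moved from 0.69 to 1.05 and miR-9-5p to -0.76. The TruSeq libraries of HP (n = 2 and 1) were too few for a value of their own. miR-4488 in HP was chosen after its value was seen.

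Among the lists in HP, the miR-183 cluster was called high by camera (adjusted p = 0.0197; 0.303 as the adjusted p with an estimated correlation), with 1 of 4 members, miR-182-5p, past the threshold adjusted over the list alone. This call ended against left uninvolved colon alone (camera adjusted p = 0.0761), with 0 members past the threshold. HOX cluster miRNAs were negative in 8 of 8 cases, 2 fell when adjusted over the list alone, and camera gave an adjusted p of 0.00294. The adjusted p of the HOX list was 0.303 with an estimated correlation. The 14q32 cluster had a median of -0.24 (camera adjusted p = 2.83e-07), the 17-92 and paralogue clusters -0.19 (0.000805), leukocyte miRNAs -0.23 (0.00113), the list lowered in colorectal tumours -0.21 (0.00113), the 29 and 30 families -0.21 (0.00464), the p53 and methylation-silenced list -0.14 (0.0197) and fibroblast and stromal miRNAs -0.10 (0.0197), where the median of all miRNAs was -0.10. With an estimated correlation the adjusted p was 0.452 for fibroblast and stromal miRNAs and 0.303 for each of the others. Against left uninvolved colon alone, camera also called smooth muscle (adjusted p = 0.00138), let-7 (0.00160), enteroendocrine and neural (0.0178) and 200 family miRNAs (0.0216) low, with adjusted p-values from 0.260 to 0.372 with an estimated correlation. The medians then lay at -0.38 for 14q32, -0.30 for 17-92, -0.21 for the p53 list and -0.18 for stromal miRNAs, beside -0.16 for all miRNAs, and 2 of 8 HOX cluster miRNAs were positive. The abundant miR-21-5p, miR-143-3p, miR-192-5p and miR-375 had log2 fold changes of 0.22, -0.14, -0.06 and 0.14 in HP, with SE from 0.18 to 0.27. Without libraries under 2000000 reads the value of miR-21-5p turned to -0.0602, and with the same sum per library that of miR-192-5p turned to 0.00312. Against left uninvolved colon alone miR-21-5p stood at -0.0867 and miR-375 at -0.0329.

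AP was compared with its own uninvolved colon (n = 10 and 10) to set the conventional adenoma beside the serrated polyps. miR-549a averaged 49.8 ± 52.5 in AP and 1.98 ± 1.81 in uninvolved colon (SD), an 8.18-fold difference (95% confidence interval 3.37 to 19.9) with the higher value in AP in 9 of 10 subject codes. miR-135b-5p averaged 1053 ± 1188 against 110.1 ± 105.0, a 5.01-fold difference (2.31 to 10.8) seen in 8 of 10, and miR-31-5p 244 ± 442 against 49.2 ± 46.9. Lower in AP in 10 of 10 subject codes were miR-195-5p, a member of the list lowered in colorectal tumours, at a log2 fold change of -0.72 ± 0.17 (SE), miR-130a-3p at -0.61 ± 0.15 and miR-9-5p at -0.90 ± 0.23. miR-215-5p, an intestinal epithelial miRNA, averaged 66381 ± 36470 in AP and 125214 ± 81648 in uninvolved colon. By limma, 0 of 644 miRNAs passed in AP and 74 had an unadjusted p under 0.05, with adjusted p-values of 0.0714 for miR-549a, 0.103 for miR-135b-5p, miR-195-5p and miR-130a-3p, 0.109 for miR-135b-3p, 0.153 for miR-9-5p, 0.243 for miR-215-5p and 0.656 for miR-31-5p. With subject code as a fixed or a random block, limma called 5 and 4 miRNAs in AP. edgeR gave 3 miRNAs (92 unadjusted), all higher in AP, namely miR-549a (15.1-fold, adjusted p = 0.00474), miR-135b-5p (7.64-fold, adjusted p = 0.0467) and miR-135b-3p. DESeq2 gave 5 (92 unadjusted), these and miR-31-5p on the higher side and miR-195-5p on the lower. On reads summed per subject code edgeR called the same 3, and DESeq2 called them with miR-195-5p and miR-130a-3p but not miR-31-5p. Within NEBNext A and B (n = 5 and 5 in each), miR-549a had log2 fold changes of 1.18 ± 0.82 and 4.89 ± 0.51 (limma adjusted p = 0.000359 in B), and miR-135b-5p 1.05 ± 0.55 and 3.59 ± 0.71. Against right uninvolved colon alone (n = 10 and 7), the log2 fold change of miR-549a moved from 3.03 to 2.44 ± 0.63 and that of miR-135b-5p from 2.32 to 2.73 ± 0.60. miR-549a lies at chromosome 15, 80841993 to 80842013 (hg38), on the minus strand opposite CEMIP. miR-549a, miR-135b-3p, miR-130a-3p, miR-195-5p and miR-584-5p in AP were chosen after their values were seen.

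The list raised in colorectal tumours was called high in AP as well, with 13 of 18 members positive, 4 that rose when adjusted over the list alone and a camera adjusted p of 0.00361. The adjusted p of this list was 0.248 with an estimated correlation. Its members included miR-224-5p (log2 fold change 0.70 ± 0.25) and miR-584-5p (0.97 ± 0.32). The miR-183 cluster was called high (camera adjusted p = 0.00195; adjusted p = 0.217 with an estimated correlation), with 1 member, miR-183-5p, that rose when adjusted over the list alone. miR-183-5p stood at 0.58 ± 0.20 and miR-182-5p at 0.46 ± 0.21. Within NEBNext A and B, miR-183-5p had 0.13 ± 0.25 and 1.04 ± 0.26 (SE), miR-182-5p 0.04 ± 0.29 and 0.89 ± 0.26, miR-96-5p -0.03 ± 0.24 and 1.14 ± 0.37, miR-224-5p 0.29 ± 0.35 and 1.11 ± 0.30, miR-584-5p 0.43 ± 0.51 and 1.51 ± 0.30 and miR-31-5p 0.32 ± 0.97 and 2.12 ± 0.58, each higher in B. Stromal and muscle miRNAs stood low as groups, and without a block for subject code no member passed the threshold adjusted over the list alone. With subject code as a fixed block, 8 of 14 fibroblast and stromal miRNAs fell by that measure, and 0 of 9 smooth muscle miRNAs. Without it, 13 of 14 fibroblast and stromal miRNAs were negative, with a median of -0.44. The camera adjusted p of this list was 6.34e-06, and 0.217 with an estimated correlation. Among its members were miR-100-5p at -0.44 ± 0.21 and miR-10b-5p at -0.61 ± 0.28. In NEBNext A and B miR-100-5p had -0.17 ± 0.28 and -0.71 ± 0.30, and miR-10b-5p -0.30 ± 0.37 and -0.92 ± 0.37. The median of all miRNAs was -0.07. Of the smooth muscle list, 8 of 9 were negative (camera adjusted p = 0.00415; adjusted p = 0.227 with an estimated correlation), with miR-143-3p at -0.21 ± 0.18 and miR-145-5p at -0.37 ± 0.26. The 14q32 cluster had a median of -0.27 (camera adjusted p = 4.30e-09), the list lowered in colorectal tumours -0.28 (3.21e-05), the 29 and 30 families -0.19 (0.00226), leukocyte miRNAs -0.15 (0.00797), intestinal epithelium -0.28 (0.0322) and enteroendocrine and neural miRNAs -0.26 (0.0495). In that order the adjusted p with an estimated correlation was 0.217, 0.217, 0.227, 0.248, 0.227 and 0.217. Adjusted over the list alone, miR-195-5p fell in the list lowered in colorectal tumours, miR-215-5p in intestinal epithelium and miR-9-5p in the enteroendocrine and neural list. Against right uninvolved colon alone the calls of smooth muscle (camera adjusted p = 0.214), intestinal epithelium (0.214) and enteroendocrine and neural miRNAs (0.142) ended, HOX cluster miRNAs were called low (0.000351; adjusted p = 0.269 with an estimated correlation) and red blood cell miRNAs high (0.0123; adjusted p = 0.330 with an estimated correlation), and the median was -0.09 for 14q32 (0.0287; adjusted p = 0.479 with an estimated correlation) and -0.17 for the list lowered in colorectal tumours (0.00373; adjusted p = 0.330 with an estimated correlation). The list raised in colorectal tumours then had 3 members that rose adjusted over the list alone, and the miR-183 cluster, the list lowered in colorectal tumours and intestinal epithelium had 0 members past that threshold.

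**Figure D2:**
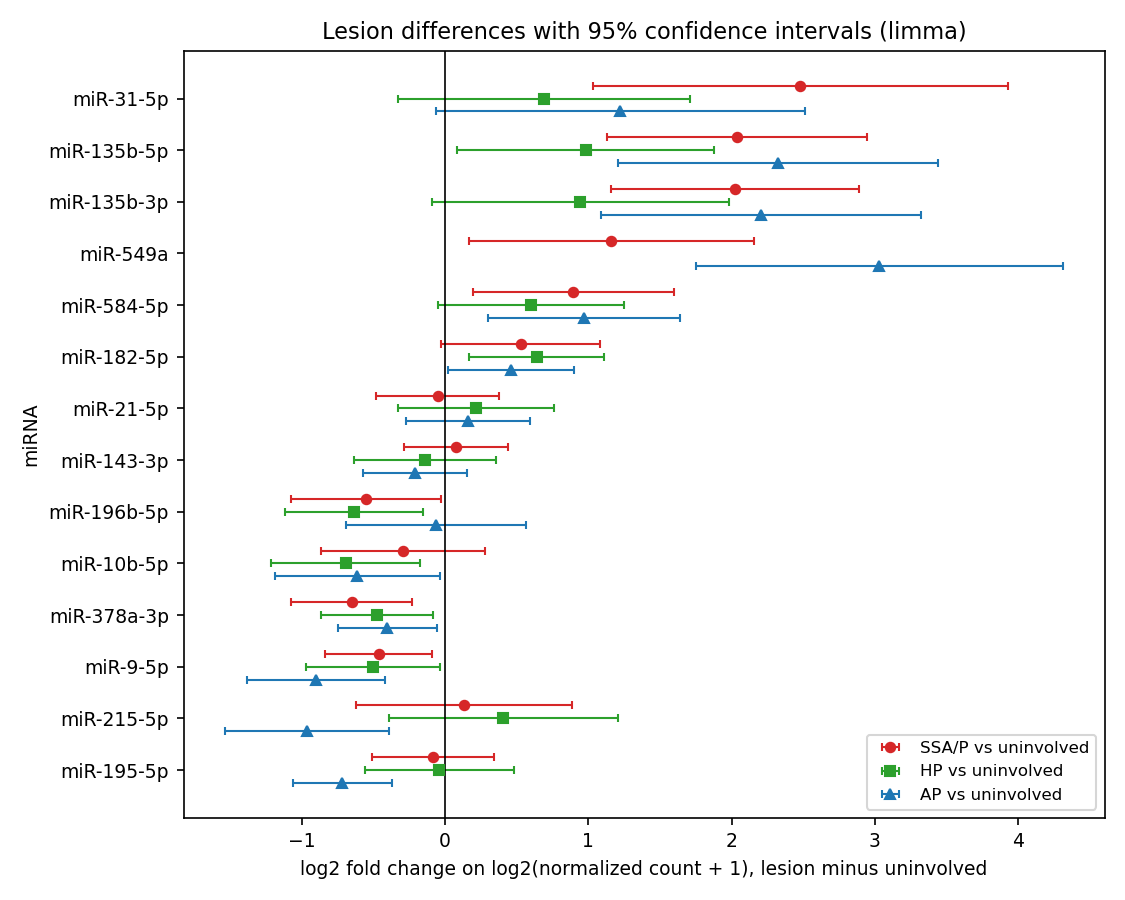
Log2 fold changes on the log2(normalized count + 1) scale, lesion minus uninvolved colon of the same table, with 95% confidence intervals from limma. miR-135b-5p lay at 2.04 in SSA/P, 0.98 in HP (0.29 against left uninvolved colon alone) and 2.32 in AP, while miR-215-5p lay at 0.13, 0.41 and -0.96 and miR-549a has no value in HP.

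Whether a lesion's difference from uninvolved colon was larger in one polyp type than in another was tested directly, with no term for cohort. The serrated polyposis cohort gave 10 of 16 SSA/P libraries, 2 of 14 HP libraries and 0 of 14 AP libraries. Polyp type and cohort are thus mixed in these differences, and their shares were not tested. miR-31-5p differed by 1.79 ± 0.92 (log2, SE) more in SSA/P than in HP and by 1.26 ± 1.02 more in SSA/P than in AP. miR-135b-5p differed by 1.06 ± 0.66 more in SSA/P than in HP, and for SSA/P minus AP its value was -0.29 ± 0.73. For miR-549a, SSA/P minus AP was -1.87 ± 0.81, and for miR-215-5p, HP minus AP was 1.37 ± 0.52. The SSA/P and HP tables shared 2 subject codes, which the fit took as separate, and without them SSA/P minus HP was 3.20 ± 0.83 for miR-31-5p (limma adjusted p = 0.477) and 1.59 ± 0.68 for miR-135b-5p, with 0 miRNAs called (10 unadjusted). The limma test called 0 of 618 miRNAs for SSA/P minus HP (7 at an unadjusted p under 0.05), 0 of 609 for SSA/P minus AP (24) and 0 of 610 for HP minus AP (23). Among the 3 tests the lowest limma adjusted p of a miRNA was 0.991. That of any feature was 0.350, for the piRNA hsa_piR_000796 in SSA/P minus AP (-1.28 ± 0.33), which was chosen after its value was seen, and no count model was run on these differences. For simulated 4-fold differences the same fits called 53%, 51% and 45% of the changed features, in the same order.

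In control colon the right side was compared with the left (n = 15 and 15). miR-615-3p, which is encoded in the HOXC cluster, rose 23.6-fold on the right (95% confidence interval 12.7 to 43.9), from 9.85 ± 13.7 on the left to 176 ± 97.6 (SD), and was higher on the right in 15 of 15 subject codes (limma adjusted p = 9.66e-09). miR-375, an enteroendocrine miRNA, fell from 80321 ± 34564 on the left to 36317 ± 14859 on the right (log2 fold change -1.15 ± 0.18 SE, limma adjusted p = 0.000214). miR-135b-5p fell from 189 ± 117 to 54.2 ± 32.6 (-1.73 ± 0.33, limma adjusted p = 0.00347), opposite to its direction in SSA/P and AP. miR-552-3p (-1.48 ± 0.35, limma adjusted p = 0.0282), miR-654-3p of the 14q32 cluster (-1.03 ± 0.24, 0.0282) and miR-3065-3p (-1.27 ± 0.32, 0.0497) also fell. miR-375, miR-135b-5p and miR-552-3p were lower on the right in 15 of 15 subject codes, and miR-654-3p and miR-3065-3p in 14. These 6 miRNAs, 1 up and 5 down, were the ones that passed among 638, and 97 had an unadjusted p under 0.05. With subject code as a block, limma called 53 miRNAs, 11 up and 42 down, which included the 6. The added ones included miR-31-5p (0.97 ± 0.27 without the block, adjusted p = 0.0951; adjusted p = 0.0157 with it), miR-203a-3p, miR-210-3p, miR-196b-3p and miR-1269a (adjusted p with the block 0.00795, 0.0157, 0.0169 and 0.0124). Of these, miR-31-5p, miR-196b-3p and miR-1269a were higher on the right. miR-3065-3p, miR-203a-3p, miR-196b-3p, miR-1269a, miR-494-3p and miR-142-3p were chosen after their values were seen.

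**Figure D3:**
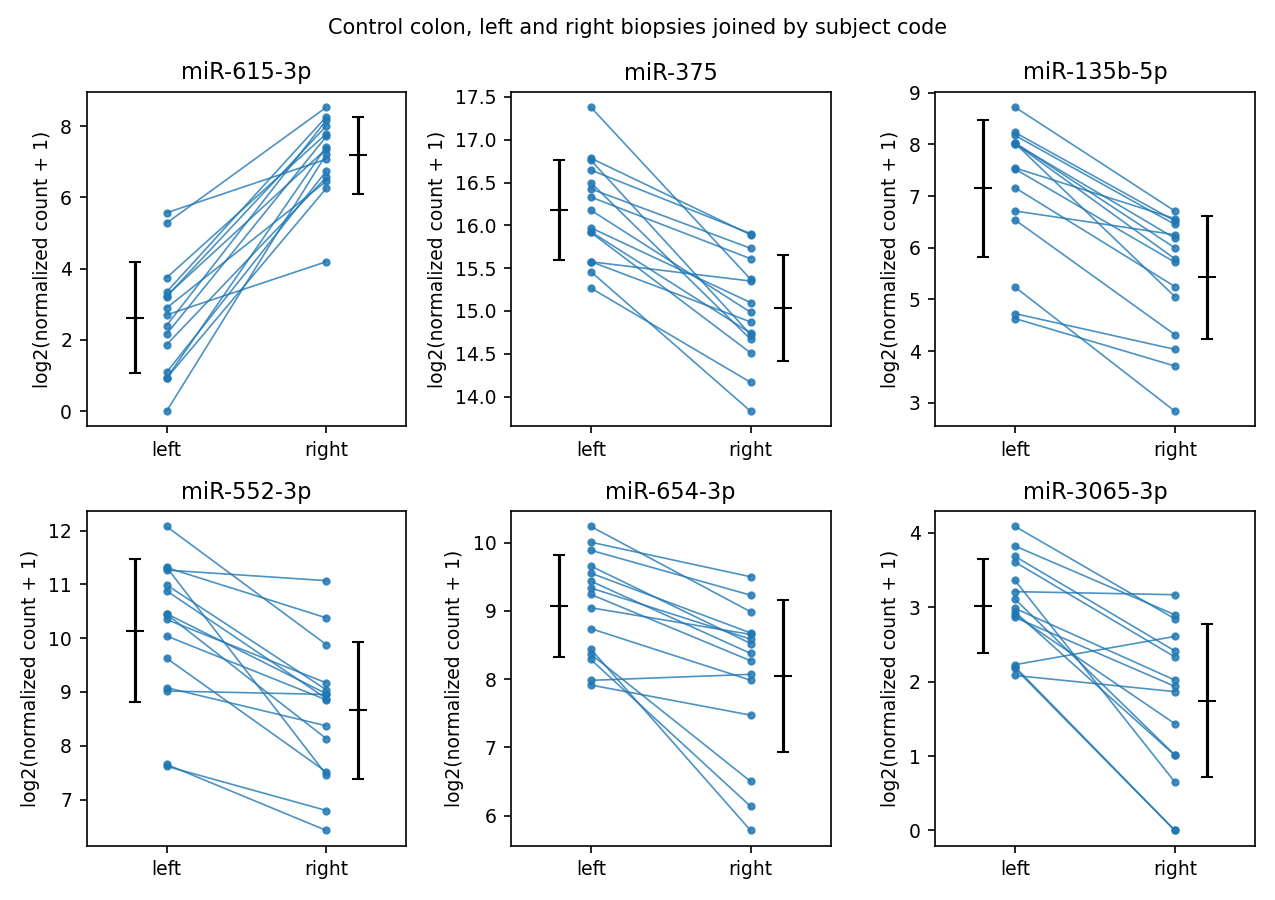
Log2(normalized count + 1) of the 6 called miRNAs in left and right control colon, with a line for each of the 15 subject codes and the mean and SD of each side as bars. miR-615-3p averaged 2.62 ± 1.56 on the left and 7.18 ± 1.08 on the right.

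miR-615-3p lies at chromosome 12, 54034010 to 54034031 (hg38), on the plus strand in introns of HOXC4 and HOXC5. miR-375 lies at chromosome 2, 219001648 to 219001669, and miR-552-3p at chromosome 1, 34669614 to 34669634, both on the minus strand outside other annotated genes. miR-654-3p lies at chromosome 14, 101040269 to 101040290, on the plus strand. miR-3065-3p, at chromosome 17, 81125926 to 81125948 on the plus strand, overlaps miR-338-5p on the opposite strand, and where counting ignores strand the reads of both cannot be told apart. The strand setting is not given in the sources used here. Within NEBNext A (n = 7 and 7) and NEBNext B (n = 8 and 8), miR-615-3p had log2 fold changes of 4.52 ± 0.56 and 4.59 ± 0.63, miR-375 -1.16 ± 0.31 and -1.14 ± 0.22, miR-135b-5p -1.49 ± 0.63 and -1.93 ± 0.24, miR-552-3p -1.04 ± 0.54 and -1.87 ± 0.40, miR-654-3p -1.24 ± 0.45 and -0.84 ± 0.21, and miR-3065-3p -1.47 ± 0.55 and -1.10 ± 0.37. edgeR called 3 miRNAs (65 unadjusted), namely miR-615-3p, miR-375 and miR-135b-5p. DESeq2 called 7 (86 unadjusted), these and miR-552-3p, miR-146b-3p, miR-31-5p and miR-618, the last 3 of them higher on the right. miR-146b-3p and miR-618 were chosen after their values were seen. The calls of miR-552-3p, miR-654-3p and miR-3065-3p ended with TMM scaling, and without the batch covariate that of miR-135b-5p ended as well.

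The 14q32 cluster stood low on the right as a group: 52 of 53 members were negative with a median of -0.51, 1 fell over all features and 10 fell when adjusted over the list alone. Camera gave an adjusted p of 2.78e-12, and the adjusted p was 0.336 with an estimated correlation. With the block, 13 members of the 14q32 list fell over all features, including miR-381-3p (limma adjusted p = 0.0325) and miR-494-3p (0.0146), and 28 adjusted over the list alone, with camera adjusted p-values of 9.06e-13 and, with an estimated correlation, 0.206. The abundant miR-127-3p of the same cluster had a log2 fold change of -0.37 ± 0.16 (limma adjusted p = 0.421). HOX cluster miRNAs were called high on the right (camera adjusted p = 3.87e-06; adjusted p = 0.336 with an estimated correlation), with 6 of 8 positive and miR-615-3p the member that rose, while miR-10b-5p had -0.03 ± 0.35 and miR-196b-5p 0.41 ± 0.34. The sign of miR-10b-5p turned with other scalings and with the count models. Leukocyte miRNAs were called high (camera adjusted p = 0.00151; 0.654 with an estimated correlation), with miR-142-3p at 0.54 ± 0.39, and red blood cell miRNAs low (0.0252; 0.447 with an estimated correlation), with miR-451a at -0.85 ± 0.44. Epithelial 200 family members were called low (0.0496; 0.773 with an estimated correlation), though miR-429 had 0.02 ± 0.42. The block brought calls over all features in each of them: miR-223-3p rose among leukocyte miRNAs, miR-486-5p fell among red blood cell miRNAs, 4 members of the 200 family fell, and miR-196b-3p joined miR-615-3p in the HOX list. The list raised in colorectal tumours had 2 members that fell, miR-135b-5p and miR-552-3p, and with the block 4 that fell and 3 that rose (not called by camera, with an adjusted p of 0.557 with the block). The median log2 fold change of all miRNAs was -0.11, and 0.04 with equal sums per library or 0.02 with TMM. The 14q32 median was then -0.36 or -0.38. miR-21-5p, miR-143-3p and miR-192-5p had log2 fold changes of 0.06, 0.13 and -0.33 (limma adjusted p = 0.991, 0.972 and 0.832). Of the other RNA classes, 2 piRNAs fell on the right. miR-223-3p was chosen after its value was seen.

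SSA/P of the serrated polyposis cohort were compared with sporadic SSA/P (n = 6 and 6). Among the lists, red blood cell miRNAs had the highest median in polyposis (1.83). Of them, miR-144-3p averaged 582 ± 442 against 54.7 ± 26.4 in sporadic SSA/P (SD), an 8.10-fold difference (log2 3.02, 95% confidence interval 1.79 to 4.25), and miR-144-5p 607 ± 484 against 109 ± 29.4. All 4 members of this list rose when adjusted over the list alone (limma), including miR-451a at a log2 fold change of 1.42 ± 0.60 and miR-486-5p at 1.29 ± 0.39, and camera gave an adjusted p of 1.64e-06. The adjusted p of the list was 0.122 with an estimated correlation. By limma over all features, 0 of 642 miRNAs passed between the cohorts and 47 had an unadjusted p under 0.05. The limma adjusted p was 0.0940 for miR-144-3p and 0.103 for miR-144-5p. With biopsies as replicates (9 of polyposis for 6 codes and 6 sporadic for 6), edgeR gave 0 miRNAs (70 unadjusted), and DESeq2 gave 5, all higher in polyposis, among them miR-144-3p (14.5-fold, adjusted p = 4.52e-06), miR-144-5p and miR-338-5p, the last chosen after its value was seen. On reads summed per subject code edgeR gave 0 and DESeq2 5, with adjusted p-values of 5.10e-05 for miR-144-3p, 0.00388 for miR-144-5p and 0.0197 for miR-338-5p. miR-31-5p had a log2 fold change of 1.57 ± 1.34, miR-135b-5p 1.27 ± 0.68 and miR-182-5p 0.84 ± 0.50 between the cohorts. Without the batch covariate miR-144-3p kept a value of 3.03, while miR-451a moved to 0.47, miR-135b-5p to 0.00821 and miR-182-5p to -0.28. Without libraries under 2000000 reads the values were 3.17 for miR-144-3p, 1.25 for miR-144-5p, 0.61 for miR-486-5p, 0.44 for miR-31-5p and 0.27 for miR-451a. Camera also called smooth muscle (adjusted p = 0.0174), stromal, 17-92, let-7 and raised-in-tumour miRNAs (0.0276 for each) and the miR-183 cluster (0.0392) high in polyposis. The adjusted p was 0.738 with an estimated correlation for each of these. These 6 calls ended without the batch covariate (camera adjusted p from 0.0939 to 0.532), and the medians then lay at -0.31 for smooth muscle, -0.57 for stromal, 0.17 for 17-92, -0.10 for let-7, -0.12 for raised-in-tumour miRNAs and -0.26 for the miR-183 cluster. The mean normalized counts of abundant members were lower in polyposis, at 377480 against 550635 for miR-143-3p, 4361 against 8857 for miR-1-3p and 60279 against 149303 for let-7g-5p. The red blood cell list kept its call without the covariate (adjusted p = 0.00963; adjusted p = 0.383 with an estimated correlation), with 2 members that rose adjusted over the list alone, while the 14q32 (0.0128) and p53 lists (0.0478) were called low (adjusted p = 0.688 for each with an estimated correlation). The median of all miRNAs was 0.12, -0.13 with equal sums per library and -0.28 without the batch covariate. NEBNext B held sporadic SSA/P alone, TruSeq (n = 3 and 1) was too small, and within NEBNext A (n = 5 and 2) miR-144-3p had a log2 fold change of 3.29 ± 0.79, miR-144-5p 1.87 ± 0.73, miR-486-5p 0.88 ± 0.52 and miR-451a 0.79 ± 0.80. In simulated data of this size, limma called 8.16% of the 98 features changed 4-fold, edgeR called 0, and DESeq2 called 46.9% of them with 8 false calls. The simulation held batch differences as random spread, so these shares can differ from those of the real fits. Going by these shares, 0 calls by limma or edgeR tell little here and DESeq2 calls may be false.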

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

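The tests in this part were chosen before the values were seen. For the 12 miRNAs named in advance, the gap between the most extreme subject code and its neighbour was compared with the whole range in each group of 4 to 10 subject codes. Of 57 such tests 5 passed Dixon's critical value, and chance gives about 1 in 20. In sporadic SSA/P (n = 6) the lowest subject code stood apart for miR-21-5p, at log2 15.50 against a median of 19.21 (gap over range 0.700), and for miR-145-5p, at 12.37 against 14.65 (0.771). In both cases it was the only TruSeq subject of that group. In SSA/P of the polyposis cohort (n = 6) the lowest stood apart for miR-215-5p, at 13.03 against a median of 16.15 (0.742), and for miR-196b-5p, at 9.42 against 11.10 (0.754), both in NEBNext A. In the uninvolved colon of the HP table (n = 10) the lowest stood apart for miR-143-3p, at 16.87 against 18.56 (0.530).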

How the results depend on the processing

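The count models on biopsies and on reads summed per subject code, the removal of libraries under 2000000 reads, uninvolved colon of one side for HP and AP, the lists without the batch covariate between the cohorts, the fits without the subject codes that SSA/P and HP share and the swaps within codes were chosen after seeing the data; all other alternatives were planned. The cause of each change below was not tested. For SSA/P the 0 called miRNAs became 2 with flow cell as the covariate, 1 with right uninvolved colon alone, 4 with each biopsy as a replicate, 2 without libraries under 2000000 reads, 4 in edgeR and 13 in DESeq2 (4 and 4 with reads summed per subject code). For AP they became 1 with a pseudocount of 10 (miR-549a), 1 with each biopsy as a replicate, 3 in edgeR and 5 in DESeq2 (3 and 5 with summed reads). For HP and the 3 differences of lesion effects the count stayed at 0 in limma under every alternative run, and for HP also in edgeR and DESeq2. For the cohorts DESeq2 gave 5, and 5 with summed reads, with 4 miRNAs in both sets. For control colon the 6 called miRNAs became 3 with TMM scaling, 2 without the batch covariate, 18 with flow cell as the covariate and 3 in edgeR. All of the 6 were among the 18, and the 3 with TMM, the 2 without the covariate and the 3 in edgeR were among the 6.

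With subject code as a fixed replicate block, the counts became 1 for SSA/P (miR-135b-3p), 5 for AP (miR-549a and miR-135b-5p, adjusted p = 0.0290 for each, higher, and miR-9-5p, 0.0324, miR-215-5p, 0.0473, and miR-195-5p, 0.0494, lower) and 53 for control colon, and with a random block 13 (10 higher), 4 and 54. HP and the differences of lesion effects stayed at 0. For the lesions the correlation within codes was less uniform than in control colon, which does not show that a code fails to link biopsies. The main limma fit took the lesion and uninvolved means of a code as independent. Own-code correlations had medians of 0.255 for SSA/P, 0.258 for HP and 0.437 for AP, against -0.0135, 0.00329 and -0.0189 between other codes. They were above 0.1 in 11 of 12 codes for SSA/P, 7 of 10 for HP and 9 of 10 for AP, and the best match was a code's own in 6, 4 and 7. With lesion and uninvolved colon swapped within codes, 4 of 100 splits of SSA/P gave as many miRNAs at an unadjusted p under 0.05 as the real 78 (highest other 92), 12 of HP (real 48, highest other 165) and 1 of AP (real 113, highest other 94). The called miRNAs of the block were less apart from the swaps. For SSA/P 5 splits gave as many as the real 1 (highest other 3), and for AP 2 gave as many as the real 5 (highest other 9). A split of HP gave 40 beside the real 0. In control colon the members past the threshold adjusted over the list alone went from 1 to 4 for red blood cell miRNAs with the block, and from 0 to 2 for leukocyte miRNAs. In AP, those that fell went from 0 to 8 for fibroblast and stromal miRNAs and from 0 to 5 for 14q32. They went from 0 to 5 for the 29 and 30 families and from 1 to 4 for intestinal epithelium, where 2 rose. The miR-183 cluster of AP went from 1 to 3 that rose, and red blood cell miRNAs of SSA/P from 1 to 4. In HP the miR-183 cluster went from 1 to 0 and HOX cluster miRNAs from 2 to 0.

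Signs turned as follows. miR-21-5p in SSA/P was 0.0244 in NEBNext libraries, 0.0592 in edgeR and 0.0676 in DESeq2, and 0.142 and 0.121 with reads summed per subject code. In HP, miR-21-5p was -0.0602 without libraries under 2000000 reads and miR-192-5p 0.00312 with equal sums, and against left uninvolved colon alone miR-21-5p was -0.0867 and miR-375 -0.0329. In AP, miR-192-5p was 0.11 against right uninvolved colon alone. In control colon miR-10b-5p was 0.13 with equal sums, 0.11 with TMM, 0.0160 in edgeR, 0.0233 in DESeq2 and 0.14 without libraries under 2000000 reads. miR-182-5p between the cohorts was -0.28 without the batch covariate. In NEBNext libraries, miR-195-5p for SSA/P minus HP was 0.0248 and miR-135b-5p for SSA/P minus AP 0.0741. Among the values of single miRNAs under an alternative, 1602 kept their side of the threshold, 104 came to pass it and 17 no longer did. Of the list tests, 37 were called with the preset correlation. With an estimated correlation each of these calls ended and no list was called, with 0.122 as the lowest adjusted p (camera, red blood cell list between the cohorts). No list that camera called had a median of the other sign with equal sums per library or TMM. The miR-31-5p difference in SSA/P ranged from 2.29 to 3.68 and the miR-615-3p difference in control colon from 3.20 to 4.77.

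Leaving out the filter added no miRNA in SSA/P and AP and tests nothing there. A mean of at least 50 left 360 of 650 miRNAs in SSA/P and 356 of 644 in AP, without miR-135b-3p and miR-549a in both and without miR-31-3p in SSA/P, and the count stayed at 0 (23 and 47 unadjusted). The planned tests across tables were not run, since the tables were normalized separately. Rescaled versions of them were tried after values had been seen, were dropped for that reason, and are not reported. No simulation varied depth. At the depth of these libraries simulated 2-fold changes were called in 27% of cases for SSA/P, 16.2% for HP and 1.02% for the cohorts (n = 6 and 6), whose libraries are among those of SSA/P. Low miRNAs such as miR-31-3p, at a mean normalized count of 1.01 in the uninvolved colon of SSA/P, rest on few reads.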

Other observations

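The overlap tests, the swaps within codes and, for the 14q32 difference, the tests of depth as a part and of a batch shift were chosen after the results were seen, and the other tests in this part before. miRNAs named from the overlaps were chosen after their values were seen. SSA/P shared more of its highest miRNAs with AP and with HP than independent lists would. At an unadjusted limma p under 0.05, SSA/P and AP shared 6 miRNAs on the higher side, miR-135b-5p, miR-135b-3p, miR-549a, miR-584-5p, miR-23a-5p and miR-4485-3p, where 0.591 would be shared by independent lists (one-sided Fisher's exact p = 8.17e-06). SSA/P and HP shared 4, miR-135b-5p, miR-27a-5p, miR-4488 and miR-3614-5p, against 0.411 (exact p = 0.000436). HP and AP shared miR-135b-5p, miR-182-5p, miR-183-5p and miR-224-5p, 4 against 0.395 (exact p = 0.000369). On the lower side, SSA/P and HP shared miR-378a-3p, miR-196b-5p and miR-9-5p, 3 against 0.367 (exact p = 0.00453), HP and AP shared 5 against 1.19 (exact p = 0.00400), and SSA/P and AP shared 2 against 1.24 (exact p = 0.357). miR-378a-3p and miR-9-5p were in all 3 sets. With uninvolved colon of one side, right for SSA/P and AP and left for HP, SSA/P and AP shared 5 on the higher side against 0.870 (exact p = 0.00105), the 6 without miR-4485-3p. SSA/P and HP then shared 7 against 0.612 (exact p = 4.36e-07), namely miR-27a-5p, miR-3141, miR-3614-5p, miR-4488, miR-4492, miR-4508 and miR-4516. miR-135b-5p was not among them, at 0.29 ± 0.40 (log2, SE) in HP against left uninvolved colon. HP and AP then shared 0 against 0.594. On the lower side the counts were 4 against 1.47 for SSA/P and HP (exact p = 0.0503), 5 against 2.85 for HP and AP (exact p = 0.145) and 1 against 0.791 for SSA/P and AP (exact p = 0.561), with miR-9-5p in each set. The SSA/P and HP tables shared 2 subject codes. Without them, and with both sides pooled, SSA/P and HP shared 7 on the higher side against 0.53 (exact p = 6.14e-08). These were miR-27a-5p, miR-182-5p, miR-215-3p, miR-3141, miR-3196, miR-4488 and miR-4492, without miR-135b-5p or miR-3614-5p. On the lower side 2 were shared against 1.24 (exact p = 0.357), miR-378a-3p and miR-9-5p without miR-196b-5p. The tables hold separate uninvolved libraries, but miRNAs of a hairpin or cluster are not independent of each other.

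Side by side and with no test, since the tables are scaled separately, the mean log2 value of miR-615-3p was 7.18 in right and 2.62 in left control colon, 5.59 in SSA/P and 6.07 in its mostly right uninvolved colon, and 2.96 in HP and 3.15 in its mostly left uninvolved colon. miR-31-5p averaged 8.31 in SSA/P, 5.06 in HP and 6.46 in AP, and 5.31 in right and 4.34 in left control colon.

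The fall of 14q32 miRNAs in right control colon averaged -0.50 ± 0.11 (log2, SE, n = 15) over the list and was seen in 14 of 15 subject codes. The fibroblast and stromal list averaged -0.0183, and the difference of -0.478 between the lists (permutation p = 0.000260) argues against less stroma as the cause. The stromal list kept its HOX members in this test, among them miR-10b-5p with a log2 fold change of -0.03. Depth as the whole cause is argued against by the fit at equal reads given below. In the codes whose right library was deeper the mean was -0.267 ± 0.104 (SE, n = 7, exact p = 0.0625). That mean was below 0 by more than 2 SE, the limit set in advance, but its exact p does not decide the question on its own. Where the right library was shallower the mean was -0.697 ± 0.156 (SE, n = 8, exact p = 0.00781). The test of depth had met both outcomes written for it and was divided after the result was seen: the difference followed the log2 ratio of reads over subject codes (Pearson r = 0.791, permutation p = 0.000540; Spearman rho = 0.704, permutation p = 0.00439; r = 0.756 without the 2 farthest), so depth may account for a part, with -0.41 ± 0.07 (SE) fitted at equal reads. The fibroblast and stromal list difference also followed the log2 ratio of reads (r = 0.614), so this relation is not particular to 14q32. A shift of level between the NEBNext batches cancels by design, since both biopsies shared a batch in 15 of 15 codes. The fall of -0.496 within codes is the pattern itself and adds no separate support. By batch the list was lower at -0.403 ± 0.191 in 6 of 7 codes of A (exact p = 0.0625) and -0.578 ± 0.125 in 8 of 8 of B (exact p = 0.00781). A fall in A on its own thus stays open, and a difference between the colon sides remains a hypothesis.

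For the high miR-31-5p and miR-135b-5p of SSA/P, the TruSeq kit as the cause is argued against by NEBNext libraries alone, where the mean of both log2 differences was 2.44 ± 0.85 (SE, n = 10, permutation p = 0.0234). Of the pair, miR-135b-5p gave 2.40 ± 0.61 there (permutation p = 0.00977), and miR-31-5p 2.49 ± 1.18 with 3 of 10 codes below 0 (permutation p = 0.0703), beside 2.48 over all libraries and 2.65 ± 0.84 (limma, n = 7 and 7) within NEBNext A alone. A larger share of epithelium is argued against by the 200 family, which averaged -0.173 (difference from both miRNAs 2.43, permutation p = 0.00928). A biological difference of the lesion remains a hypothesis, found and tested on the same data.

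miR-196b-5p, encoded in the HOXA cluster, averaged -0.507 ± 0.143 (log2, SE, n = 21) in SSA/P and HP relative to uninvolved colon, with a code that had both counted once. SSA/P alone gave -0.553 ± 0.152 (10 of 12 codes below 0, permutation p = 0.00635) and HP alone -0.455 ± 0.280 (7 of 10, permutation p = 0.143). Less stroma is argued against by the stromal list without HOX members, at 0.00893 (permutation p of the difference 0.0107). Whether biopsies from different sites account for it cannot be told apart from a lesion difference, since the 12 subject codes with matching site codes gave -0.345 ± 0.194 (permutation p = 0.101).

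Other splits of the samples that ignored subject codes were drawn, 100 in each case with the real one included, and miRNAs at an unadjusted p under 0.05 counted. For AP 3 splits gave as many as the real 74, which argues against chance but does not exclude it, since another split gave 94. These splits give no argument against chance for SSA/P (31 splits gave as many as the real 38, highest other 146), HP (40; real 30, highest other 106), control colon without the block (6; real 97, highest other 201) or the cohorts (16; real 47, highest other 134). The same holds for SSA/P minus HP (62; real 7, highest other 85), SSA/P minus AP (11; real 24, highest other 61) and HP minus AP (21; real 23, highest other 44). Some splits gave several times the real count, which a structure of the samples outside the groups or miRNAs that vary together would give, and neither was tested. With right and left swapped within subject codes of control colon, as the pairing there allows, 1 of 100 splits, the real one, gave as many as its 162, with 125 as the highest other, and the 53 calls stood beside at most 1 in another split. In the lesions, where not every code correlated above 0.1, such swaps gave as many as the real split in 4 of 100 for SSA/P (real 78). The counts were 12 for HP (real 48) and 1 for AP (real 113), the real one included.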
